A study of Mus musculus with 12 samples.

How the data were processed

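Gene expression was measured by RNA sequencing in 12 libraries of sorted CD44+ CD8+ mouse T cells, 4 each from the spleen, from photoconverted (Kaede red) cells of the tumor-draining lymph node (egressed) and from photoconverted cells of YUMMER1.7 tumors (tumor-retained). Per the labels' protocols, RNA was obtained with Takara lysis solution and libraries were made from total RNA with the SMART-Seq v4 kit for ultra-low input by a service company, which also sequenced them. The kit copies polyadenylated RNA at full length by template switching and adds no molecular identifiers, so counts of reads are not counts of molecules, and intervals and floors printed here cover counting error only. The labels do not say that strand was kept, so reads of overlapping genes on opposite strands cannot be told apart. The submitters' processing notes name cutadapt 2.5, Bowtie2 2.5.1, STAR 2.7.3a and Cufflinks 2.2.1 and the genome build mm10, without the role or order of the tools. The program that counted reads, the annotation and the program that normalized the values are not given in the sources used here.

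The authors deposited a table of raw counts per gene symbol (48397 symbols by 12 libraries) and a table of log2 normalized values. Per the file headers and values, the deposited log2 value equals log2(count / size factor + 1) with 1 size factor per library (largest difference 5.1e-09), and these factors were 1.097 to 1.103 times the median-of-ratios factors computed from the counts. Totals were 31.4, 29.8, 33.4 and 27.3 M counts (M, mega) for spleen libraries 1 to 4, 24.6, 24.8, 29.2 and 22.7 M for egressed and 33.5, 25.6, 32.4 and 36.3 M for tumor-retained libraries. All columns were matched to samples. 27 symbols had been turned into dates by a spreadsheet, 24 of them tested, with at most 0.227% of the counts of a library, and these were kept in the tests but are not named. 46368 symbols (95.81%) were found in GENCODE M21, which gave positions on mm10. No 2 libraries were copies of each other (lowest chi-square per degree of freedom between libraries of a group 19.7).

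Counts were analysed with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr (21457 kept), scaled with TMM and fitted in 1 quasi-likelihood model of the 3 groups with no block, and contrasts were tested with glmQLFTest and Benjamini-Hochberg adjustment at 0.05. The common biological coefficient of variation was 1.21, with 9 residual degrees of freedom and 3.19 prior degrees of freedom at the least, and log2 CPM used a prior count of 2. Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01, 2-sided, over 29 of 30 lists, since the erythroid and platelet list had fewer than 5 tested genes. 33 genes stand in more than 1 list. The lists, the tests, the settings compared in the closing section and the rule for the genes named were fixed before the data were examined. That rule names, per comparison, the 8 highest and 8 lowest log2 fold changes among genes that passed, moved the same way in 4 replicate numbers and reached 10 CPM in the higher group (no predicted genes, clones or receptor segments), 15 genes of the study's question, up to 4 members with the smallest p of each list that passed, and the 3 most abundant members of each list of other cells or technical signs. Of these, the text gives the genes of the study's question and the members that passed first, and values of the others where they bear on a list, except that some of these genes are not reported here.

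Lists covered inhibitory and costimulatory receptors, exhaustion regulators, stem-like and memory genes, homing and tissue exit, chemokine receptors, residency, antigen receptor response, dissociation stress and immediate early genes, cytotoxic molecules, circulating effector genes, innate-like receptors, integrins, cell cycle, type I interferon, glycolysis, hypoxia, oxidative phosphorylation, cholesterol synthesis, endoplasmic reticulum stress, ribosomal proteins, CD8 T cell identity, and markers of B cells, macrophages, dendritic cells, granulocytes, CD4 and regulatory T cells, natural killer and gamma delta T cells, melanoma cells and stromal cells. The design text says that tissues came from 4 mice but not that libraries of the same number share a mouse; this was assumed where mice are named here, and the main test does not use it. The deviations of same-numbered libraries from their group means correlated at -0.124 to 0.117, and 5 of 24 best matches were to the library's own number. A fit with the replicate number as a block is given beside a result where it changed it. For overlaps of calls, unchanged groups were simulated against the same libraries 10 times, and the shared libraries were divided 2 and 2 in 6 ways. The position of egressed cells is the slope through the origin of a mouse's egressed minus spleen differences on the tumor-retained minus spleen differences of the other 3 mice, over genes that passed without that mouse.

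Alternatives fixed beforehand were DESeq2 size factors in edgeR, library size alone, no low-count filter, DESeq2 1.42.0, limma on the deposited log2 values, a fit of the 2 compared groups only, the replicate block, glmTreat for more than 1.5-fold, each library left out, camera with estimated correlation and fry. A fit without tumor-retained libraries 3 and 4, a fit without egressed libraries 3 and 4 and tumor-retained library 1, and limma-voom with library weights were added after seeing the data. The libraries left out in these fits were singled out by measured values: libraries 3 and 4 by transcripts of other cells and Y-linked transcripts, and the other 3 by the number of genes detected. Tests of where those transcripts come from use the same values, and their bounds were written after the results, so their counts of marker genes describe the libraries and decide nothing. Each analysis was tested on simulated counts of 21457 genes with known changes. Of genes changed 2-fold, 4-fold and 8-fold, 1.49%, 20.9% and 28.8% were recovered for egressed against tumor-retained. It was 1.49%, 11.9% and 25.8% for egressed and 1.49%, 13.4% and 28.8% for tumor-retained cells against spleen. With 0 false calls in each, most real changes of this size would be missed. A shifted list was recovered in each comparison, with 0 other lists called. This cannot exclude false list calls in the real libraries, where list correlations of 0.0465 to 0.711 were estimated against the preset 0.01. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.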

Results

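RNA sequencing libraries were made from CD44+ CD8+ T cells of 3 kinds, with 4 libraries of each kind, from 4 Kaede-transgenic mice that carried YUMMER1.7 tumors. YUMMER1.7 is a mouse melanoma line and CD44 is a surface marker of T cells that have met antigen. Kaede is a fluorescent protein that light converts from green to red. Tumors were photoconverted on day 11 and tissues were taken on day 12, so that a red cell found outside the tumor had been inside it at the time of conversion. Red cells of the tumor are called tumor-retained here, red cells of the tumor-draining lymph node are called egressed. CD44+ CD8+ T cells of the spleen served as the circulating population. The libraries held 27.3 to 33.4 M counts (M, mega) in spleen, 22.7 to 29.2 M in egressed and 25.6 to 36.3 M in tumor-retained cells. A count of 0 therefore allowed up to 0.0827 to 0.132 counts per M (CPM) in a library. Levels are TMM-scaled CPM as mean ± SD over n = 4 libraries, and changes are log2 fold changes ± SE from edgeR's quasi-likelihood fit. Adjusted p-values are Benjamini-Hochberg values of its test for genes and of camera for gene lists. Every gene named below as having risen or fallen moved that way in 4 of the 4 replicate numbers, with Col3a1 (3 of 4) as the exception. Counts of list members that rose or fell were not held to this. Gene positions are spans of whole genes on mm10 from GENCODE M21.

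Spleen libraries resembled each other more than the sorted red populations did. Correlations of log2 CPM between libraries of a group were at least 0.944 in spleen, 0.775 to 0.833 in egressed and 0.726 to 0.893 in tumor-retained cells. The number of genes with at least 1 count was 30658 to 32165 in spleen. It was 24310, 25916, 14927 and 15251 in egressed libraries 1 to 4 and 15296, 21306, 20560 and 20753 in tumor-retained libraries 1 to 4. The first principal component (29.8% of the variance) set egressed libraries 3 and 4 and tumor-retained library 1 apart. The second component (16.6%) set tumor-retained libraries 3 and 4 apart. These last 2 libraries also held transcripts that are abundant in macrophages and connective tissue cells. Lyz2, which encodes lysozyme of myeloid cells, measured 757.8 and 951.5 CPM in them against 3.16 and 2.76 in tumor-retained libraries 1 and 2. The collagen gene Col3a1 measured 952.3 and 642.0 against 0.28 and 36.6. The T cell coreceptor gene Cd8a stood at 648.8 and 835.1 CPM in libraries 3 and 4 and at 1146 and 1082 in libraries 1 and 2. Counts were therefore also obtained without these 2 libraries, and without the 3 libraries that detected the fewest genes, both of which were chosen after seeing the data.

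**Figure D1:**
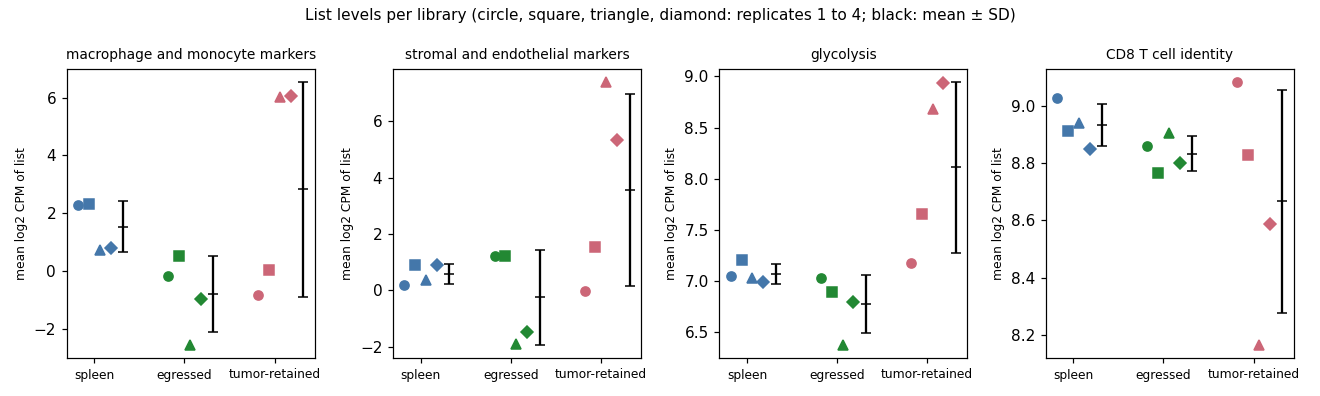
Mean log2 CPM of the genes of 4 lists (macrophage and monocyte markers, stromal and endothelial markers, glycolysis, CD8 T cell identity) in each of the 12 libraries, by group on the x axis, with symbols for replicates 1 to 4 and the mean ± SD over 4 libraries in black. Tumor-retained libraries 3 and 4 lie above the other 10 in the macrophage, stromal and glycolysis panels, at 8.69 and 8.94 against at most 7.66 for glycolysis.

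The first comparison, egressed against tumor-retained, asks how cells that left the tumor within a day differed from cells that stayed. Egressed cells held more transcripts of genes for lymphoid homing and for stem-like or memory T cells, and fewer of inhibitory receptors, residency genes, cytotoxic molecules and glycolytic enzymes. With the correlation between genes estimated rather than preset, only the inhibitory receptors of all lists kept their call (adjusted p = 0.0312, against 0.0829 for homing, 0.071 for stem-like, and 0.0529 each for residency, cytotoxic and glycolysis genes). Klf2 (chromosome 8, 72319033 to 72321656), a transcription factor that drives receptors for tissue exit, measured 664 ± 88.0 CPM in egressed and 192 ± 85.8 in tumor-retained cells (log2 fold change 1.79 ± 0.26, adjusted p = 0.00921). Pdcd1 (chromosome 1, 94038305 to 94052553), which encodes the inhibitory receptor PD-1, lay the other way at 34.7 ± 12.9 against 388 ± 155 CPM (log2 fold change -3.48 ± 0.46, adjusted p = 0.00645). Gzmb (chromosome 14, 56258838 to 56262260), for granzyme B of the killing granules, measured 131 ± 25.7 against 1859 ± 413 CPM (log2 fold change -3.82 ± 0.41, adjusted p = 0.00154). In all, 235 of 21457 tested genes changed, 109 higher and 126 lower in egressed cells, 189 of them by more than 2-fold. Scaled by library size alone, 150 genes were higher and 110 lower, and with limma 172 and 206.

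The count of changed genes depended on single libraries. It was 97, 98, 96 and 100 without spleen library 1, 2, 3 or 4, which share the spread estimate. It was 95, 141, 144 and 106 without egressed library 1, 2, 3 or 4, 487 without tumor-retained library 1 and 98 without tumor-retained library 4. A block for the replicate number, taken to pair the libraries of a mouse, gave 78 genes (34 higher, 44 lower), 76 of them among the 235. In all 56 genes passed with the block and with every library left out in turn. Without tumor-retained libraries 3 and 4 the count was 245, of which 115 were among the 235. Without the 3 libraries that detected the fewest genes it was 442, of which 119 were. Gene lists fixed before the data were examined are described next, and 21 of 29 tested lists changed, 4 higher and 17 lower in egressed cells.

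Genes of lymphoid homing and of stem-like T cells were higher in egressed cells. Of 14 homing genes tested, 3 rose and 0 fell over all genes, and 6 rose and 0 fell when adjusted over the list alone. The homing median log2 fold change was 0.46 (camera adjusted p = 6.58e-05, and adjusted p = 0.0829 with an estimated correlation). Besides Klf2, Rasgrp2, which activates the integrin regulator Rap1, rose to 187 ± 30.0 CPM from 49.3 ± 22.1 (log2 fold change 1.92 ± 0.28, adjusted p = 0.00921). Of 18 stem-like genes tested, 2 rose and 0 fell over all genes, and 7 rose and 0 fell when adjusted over the list alone. The stem-like median was 0.65 (camera adjusted p = 1.11e-08, and 0.071 with an estimated correlation). Il6ra, a subunit of the interleukin 6 receptor, rose by 1.39 ± 0.26 (adjusted p = 0.0286), but the call ended with the replicate block (adjusted p = 0.0504) and without tumor-retained libraries 3 and 4 (0.123). It also ended with any 1 library left out other than egressed 4, tumor-retained 1 or tumor-retained 2 (adjusted p up to 0.0861). S1pr1, the sphingosine 1-phosphate receptor needed to leave tissues, did not pass at 669 ± 133 against 396 ± 178 CPM (log2 fold change 0.76, 95% confidence interval 0.20 to 1.31, adjusted p = 0.155). Nor did Ccr7 pass (882 ± 181 against 453 ± 273, adjusted p = 0.171) and Tcf7 (1384 ± 78.9 against 853 ± 393, adjusted p = 0.167). Cxcr4, a chemokine receptor, measured 18.4 ± 8.20 and 19.7 ± 4.13 CPM, with a difference of -0.10 (95% confidence interval -1.15 to 0.96).

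Inhibitory receptors and regulators linked to T cell exhaustion were lower in egressed cells. Of 18 inhibitory and costimulatory genes tested, 0 rose and 4 fell over all genes, and 1 rose and 10 fell when adjusted over the list alone. The list median was -1.82 (camera adjusted p = 2.06e-11, and 0.0312 with an estimated correlation). Beside Pdcd1, Tnfrsf9, for the costimulatory receptor 4-1BB, fell to 17.1 ± 12.7 CPM from 221 ± 92.2 (log2 fold change -3.69 ± 0.56, adjusted p = 0.0104). However, without the 3 libraries that detected the fewest genes its adjusted p was 0.0578. Of 18 exhaustion-associated genes tested, 0 rose and 5 fell over all genes, and 2 rose and 8 fell when adjusted over the list alone. The list median was -1.20 (camera adjusted p = 8.4e-09, and 0.0529 with an estimated correlation). Its called members included the transcription factor genes Bhlhe40 (74.9 ± 35.3 against 551 ± 219.6 CPM, log2 fold change -2.88 ± 0.42, adjusted p = 0.00921), Id2 (-0.99 ± 0.15, adjusted p = 0.00989) and Hif1a (-2.19 ± 0.34, adjusted p = 0.0104). Havcr2, which encodes TIM-3, had means of 1.24 ± 1.99 and 111 ± 88.3 CPM and did not pass (adjusted p = 0.067). Tox, a transcription factor of exhausted cells, had 40.3 ± 16.6 and 18.8 ± 5.45 CPM (log2 fold change 1.10, adjusted p = 0.149). Of 18 antigen receptor response genes tested, 1 rose and 2 fell over all genes, and 2 rose and 3 fell when adjusted over the list alone. The list median was -0.88 (camera adjusted p = 0.0112, and 0.263 with an estimated correlation). The antigen receptor list did not pass without egressed library 2 (adjusted p = 0.0720), tumor-retained library 1 (0.0580) or tumor-retained libraries 3 and 4 together (0.0874). Nr4a1, an immediate target of antigen receptor signals, had 187 ± 57.0 and 313 ± 180.2 CPM (adjusted p = 0.351).

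Residency, cytotoxic and chemokine receptor genes moved the same way as the inhibitory receptors. Of 17 residency genes tested, 0 rose and 3 fell over all genes, and 1 rose and 7 fell when adjusted over the list alone. The residency median was -1.77 (camera adjusted p = 8.27e-12, and 0.0529 with an estimated correlation). Litaf fell to 16.5 ± 5.34 CPM from 283 ± 123 (log2 fold change -4.10 ± 0.43, adjusted p = 0.00138). Cxcr6, the receptor for CXCL16, fell to 206 ± 73.7 from 698 ± 156 (log2 fold change -1.76 ± 0.25, adjusted p = 0.00815). Itgae (104 ± 56.5 against 146 ± 50.2 CPM) and Cd69 (627 ± 203 against 341 ± 146) did not pass (adjusted p = 0.571 and 0.157). Of 19 cytotoxic genes tested, 0 rose and 2 fell over all genes, and 0 rose and 9 fell when adjusted over the list alone. The cytotoxic median was -1.14 (camera adjusted p = 7.72e-09, and 0.0529 with an estimated correlation). Of 17 chemokine receptor genes tested, 0 rose and 4 fell over all genes, and 1 rose and 6 fell when adjusted over the list alone. The list median was -1.08 (camera adjusted p = 0.000112, and 0.116 with an estimated correlation). Ccr8, at 19.2 ± 9.73 CPM in tumor-retained cells, had no count in any egressed library in the group. It was at least 169.1-fold lower there, against a floor of 3 counts per library (adjusted p = 0.0104, and 0.0697 with the block). Of 17 innate-like receptor genes tested, 0 rose and 2 fell over all genes, and 2 rose and 5 fell when adjusted over the list alone. The list median was -0.83 (camera adjusted p = 0.00016, and 0.221 with an estimated correlation). The activating receptor gene Klrk1 measured 220.1 ± 72.0 against 807 ± 199 CPM (log2 fold change -1.88 ± 0.28, adjusted p = 0.00989). The innate-like list did not pass without the 3 libraries that detected the fewest genes (adjusted p = 0.146). Of 15 circulating effector genes tested, 1 rose and 0 fell over all genes, and 2 rose and 7 fell when adjusted over the list alone. The list median was -0.69 (camera adjusted p = 0.0157, and 0.263 with an estimated correlation). It did not pass without egressed library 4 (adjusted p = 0.0770) or tumor-retained libraries 3 and 4 (0.068). Its members Klrg1 and Cx3cr1 did not pass (adjusted p = 0.942 and 0.865).

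Glycolytic enzymes were lower in egressed cells. Of 16 glycolysis genes tested, 0 rose and 9 fell over all genes, and 0 rose and 13 fell when adjusted over the list alone. The glycolysis median was -1.27 (camera adjusted p = 2.45e-20, and 0.0529 with an estimated correlation). Gapdh (chromosome 6, 125161715 to 125166467) measured 668 ± 91.4 against 1604 ± 371 CPM (log2 fold change -1.26 ± 0.17, adjusted p = 0.00639). Ldha measured 619 ± 148 against 1504 ± 359.7 (adjusted p = 0.0104, 0.062 with the replicate block and 0.0529 without the 3 libraries that detected the fewest genes). Of 17 hypoxia response genes tested, 0 rose and 1 fell over all genes, and 1 rose and 8 fell when adjusted over the list alone. The hypoxia response median was -1.95 (camera adjusted p = 1.62e-09, and 0.0829 with an estimated correlation). Mxi1, a repressor related to the MYC partner MAX, fell to 10.3 ± 1.89 CPM from 101 ± 41.5 (log2 fold change -3.29 ± 0.34, adjusted p = 0.00138). Without tumor-retained libraries 3 and 4 the median was -0.83 for glycolysis (adjusted p = 1.77e-09) and -0.92 for hypoxia (adjusted p = 0.00166). Transcripts of other cell types moved with these lists. Of 18 macrophage marker genes tested, 0 rose and 0 fell over all genes, and 0 rose and 8 fell over the list alone. The macrophage marker median was -4.42 (camera adjusted p = 2.28e-07, and 0.263 with an estimated correlation). Of 13 stromal marker genes tested, 0 rose and 0 fell over all genes, and 0 rose and 6 fell over the list alone. The stromal marker median was -4.94 (camera adjusted p = 2.82e-05, and 0.202 with an estimated correlation). Neither of these passed without those 2 libraries (adjusted p = 0.399 and 0.104). Of 12 CD4 and regulatory T cell marker genes tested, 0 rose and 1 fell over all genes, and 0 rose and 3 fell when adjusted over the list alone. The list median was -1.92 (camera adjusted p = 0.000403, and 0.0529 with an estimated correlation). The member that fell was Capg, an actin capping protein gene, at 68.0 ± 17.6 against 416 ± 180.2 CPM (adjusted p = 0.00456).

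Among the largest changes outside these lists, Slc16a5, of the monocarboxylate transporter family, measured 27.9 ± 8.94 CPM in egressed cells and had 2 counts in the tumor-retained group. This gave a ratio of 1745 (95% counting interval 483.1 to 14410, adjusted p = 5.16e-05). Dtx1 (chromosome 5, 120680202 to 120711927), for the ubiquitin ligase Deltex 1, rose to 357 ± 88.3 CPM from 18.0 ± 14.7 (log2 fold change 4.31 ± 0.60, adjusted p = 0.00752). Dapl1 (chromosome 2, 59484653 to 59505020) rose to 279.6 ± 69.7 from 15.8 ± 10.6 (log2 fold change 4.14 ± 0.40, adjusted p = 0.00137). Art2b, for an ADP-ribosyltransferase on T cells, rose by 5.41 ± 0.85 (adjusted p = 0.0119, and 0.0552 with the replicate block). Rnf24 had no count in egressed cells and was at least 100.4-fold lower (adjusted p = 0.0146, and 0.106 with the block). Esm1, a gene of endothelial cells, was at least 370.2-fold lower and Sphk1, for sphingosine kinase 1, at least 93.36-fold lower. Hmox1, Igfbp3, Mgp and Stk32c had means of at most 0.152 CPM in egressed cells and 91.6, 304, 97.7 and 13.2 CPM in tumor-retained cells. Hmox1, Igfbp3 and Mgp were highest in tumor-retained libraries 3 and 4. For Mgp, Stk32c, Esm1, Sphk1, Hmox1 and Igfbp3 the adjusted p was 0.109, 0.102, 0.123, 0.162, 0.166 and 0.275 with the block. Without tumor-retained libraries 3 and 4 it was 0.147, 0.0454, 0.0689, 0.128, 0.131 and 0.286, so that only the Stk32c call held, and this ended without the 3 libraries that detected the fewest genes (0.0875). Leaving out 1 library ended the calls in 2, 8, 6, 10, 10 and 10 of 12 cases (up to 0.126).

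**Figure D2:**
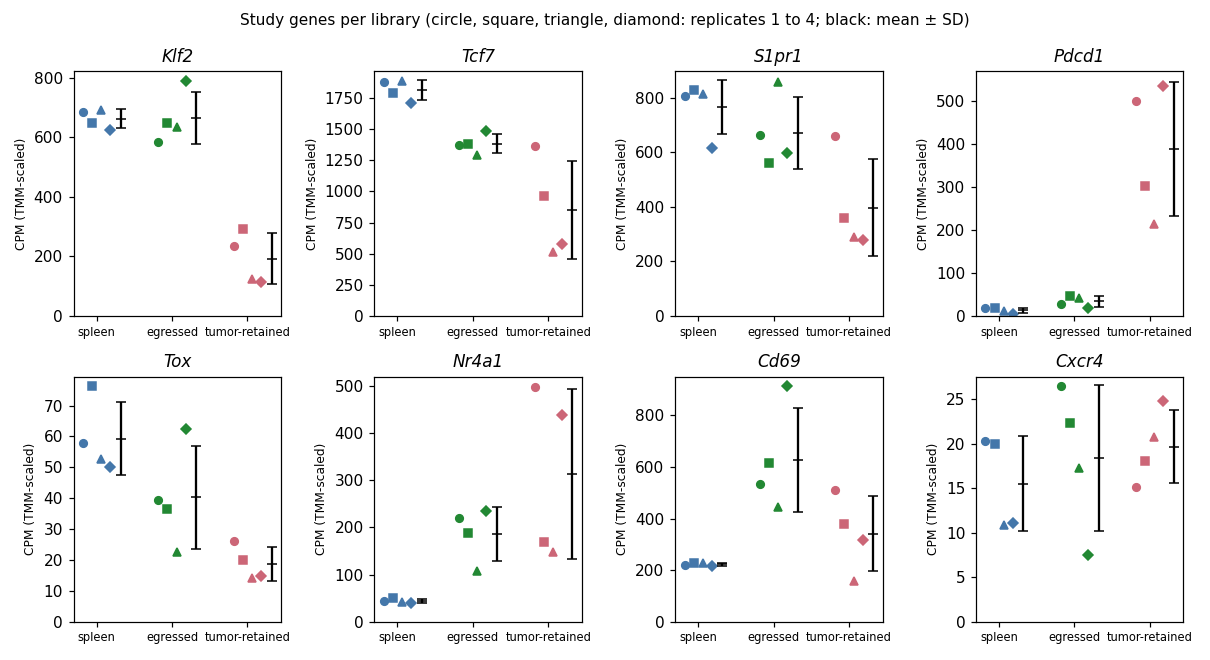
CPM (y axis, TMM-scaled) of Klf2, Tcf7, S1pr1, Pdcd1, Tox, Nr4a1, Cd69 and Cxcr4 in the 12 libraries by group (x axis), with symbols for replicates 1 to 4 and the mean ± SD over 4 libraries in black. Klf2 lies lower and Pdcd1 higher in tumor-retained cells than in the other groups, while Cxcr4 means lie between 15.5 and 19.7 CPM.

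The second comparison, egressed against spleen, asks how cells that had been in the tumor differed from circulating cells of the same surface phenotype. Egressed cells held more transcripts of immediate early and heat-shock genes, of cytotoxic molecules and of receptors shared with natural killer cells, while no homing gene passed over all genes. The innate-like receptor list lost its call with an estimated correlation (adjusted p = 0.059), and its 3 called members lost theirs with the replicate block. Fos (chromosome 12, 85473890 to 85477273), a transcription factor gene induced within minutes of stimulation, measured 889.7 ± 187 CPM in egressed and 130.4 ± 25.8 in spleen cells (log2 fold change 2.77 ± 0.22, adjusted p = 0.00057). Rgs1 (chromosome 1, 144242296 to 144249242), a regulator of chemokine receptor signals, measured 329.9 ± 67.4 against 34.7 ± 7.16 CPM (log2 fold change 3.25 ± 0.29, adjusted p = 0.000931). Tnfaip3 (chromosome 10, 19000910 to 19015657), for the NF-kappa-B inhibitor A20, measured 1162 ± 303 against 143 ± 15.4 CPM (log2 fold change 3.02 ± 0.33, adjusted p = 0.00388). Klf2 was at 664 ± 88.0 CPM in egressed and 663 ± 31.3 in spleen cells, a log2 fold change of 0.00 (95% confidence interval -0.55 to 0.56). In all, 79 genes changed, 42 higher and 37 lower in egressed cells, 58 of them by more than 2-fold. Of 29 lists, 11 changed, 10 higher and 1 lower. The median change of all genes was -0.128 with TMM scaling, 0.0302 with DESeq2 size factors and 0.00336 with library size alone. The counts were 70 higher and 20 lower with size factors and 59 and 22 with library size, but 244 and 417 with DESeq2 and 163 and 417 with limma-voom weights.

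This count too depended on single libraries. It was 5, 9, 6 and 13 without spleen library 1, 2, 3 or 4, 9, 21, 49 and 33 without egressed library 1, 2, 3 or 4, and 123 without tumor-retained library 1. The replicate block gave 23 genes (15 higher, 8 lower), 22 of them among the 79. 5 genes passed with the block and with every library left out, of which Fos, Rgs1 and Tnfaip3 are named here. Of the 79 genes, 73 passed without tumor-retained libraries 3 and 4, and 44 without the 3 libraries that detected the fewest genes. In the last case Ctsw, Fasl, Hspa1b, Nr4a1, Arf3 and Slc40a1, named below, did not pass (adjusted p up to 0.11). With an estimated correlation 2 lists passed, the immediate early and heat-shock list and the cytotoxic list.

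The list of immediate early and heat-shock genes, which was fixed as a sign of tissue handling, was higher in egressed cells. Of 20 immediate early and heat-shock genes tested, 5 rose and 0 fell over all genes, and 9 rose and 0 fell when adjusted over the list alone. The list median was 0.86 (camera adjusted p = 2.15e-34, and 0.00527 with an estimated correlation). The phosphatase gene Dusp1 rose to 488 ± 197 CPM from 94.3 ± 11.9 (log2 fold change 2.37 ± 0.31, adjusted p = 0.0115). Jun rose to 1128 ± 242 from 338 ± 49.5 (log2 fold change 1.74 ± 0.27, adjusted p = 0.0209). Hspa1a, an inducible heat-shock protein gene, rose to 424 ± 124 from 28.1 ± 13.3 (log2 fold change 3.92 ± 0.62, adjusted p = 0.0237). Hspa1b, whose sequence is almost that of Hspa1a so that reads of the pair may be split between them, rose to 1643 ± 283 from 199.7 ± 92.5 (log2 fold change 3.04 ± 0.53, adjusted p = 0.0345). Ier5l, outside the list, rose to 30.1 ± 12.8 from 1.06 ± 0.718 (log2 fold change 4.82 ± 0.60, adjusted p = 0.0106). With the replicate block the adjusted p was 0.058 for Dusp1, 0.0853 for Jun, 0.0867 for Hspa1a and 0.107 for Hspa1b, so that their calls ended. Without 1 library, calls ended for Ier5l without spleen 1 (up to 0.0649), Dusp1 without spleen 1, 2, 3 and 4 and egressed 1 (up to 0.0824), Jun without spleen 1, 2, 3 and 4 and egressed 1 and 2 (up to 0.137), Hspa1a without spleen 1, 2, 3 and 4 and egressed 1 and 2 (up to 0.138). The Hspa1b call ended without any spleen or egressed library (up to 0.171), with the adjusted p in brackets. Of 18 antigen receptor response genes tested, 1 rose and 0 fell over all genes, and 5 rose and 0 fell when adjusted over the list alone. The list median was 0.93 (camera adjusted p = 2.11e-06, and 0.0753 with an estimated correlation). Its called member Nr4a1 rose to 187 ± 57.0 CPM from 44.1 ± 5.17 (log2 fold change 2.08 ± 0.39, adjusted p = 0.0479, and 0.103 with the block). The Nr4a1 call was kept in 4 of 12 cases of a left-out library (egressed 3 and tumor-retained 1, 2 and 3) and otherwise with an adjusted p up to 0.221. Cd69, an early activation marker that also holds cells in tissue, measured 627 ± 203 against 224 ± 5.68 CPM and did not pass (log2 fold change 1.49 ± 0.31, adjusted p = 0.0687).

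Effector and innate-like receptor genes were higher in egressed than in spleen cells. Of 19 cytotoxic genes tested, 3 rose and 0 fell over all genes, and 9 rose and 0 fell when adjusted over the list alone. The cytotoxic median was 0.93 (camera adjusted p = 5.72e-20, and 0.00817 with an estimated correlation). The chemokine gene Ccl3 measured 45.1 ± 15.9 against 4.27 ± 1.27 CPM (log2 fold change 3.40 ± 0.45, adjusted p = 0.0115). Ctsw, for cathepsin W, measured 2115 ± 168 against 1112 ± 156 (log2 fold change 0.93 ± 0.15, adjusted p = 0.0237). Fasl, for the death ligand, measured 82.5 ± 40.8 against 14.8 ± 5.39 (log2 fold change 2.48 ± 0.45, adjusted p = 0.0392). Of 17 innate-like receptor genes tested, 3 rose and 0 fell over all genes, and 6 rose and 0 fell when adjusted over the list alone. The innate-like receptor median was 1.17 (camera adjusted p = 7.67e-14, and 0.059 with an estimated correlation). Those that rose were Klrd1 (log2 fold change 1.10 ± 0.18, adjusted p = 0.0259), Klrc1 (1.75 ± 0.32, adjusted p = 0.0428) and Klrk1 (1.51 ± 0.28, adjusted p = 0.0428), which encode NKG2 receptors and their partner CD94. Of 17 residency genes tested, 2 rose and 0 fell over all genes, and 6 rose and 1 fell over the list alone. The residency median was 0.73 (camera adjusted p = 2.86e-11, and 0.059 with an estimated correlation). In egressed libraries 1 to 4 the list's mean log2 CPM was 5.501, 5.581, 3.851 and 3.797, against 4.32 to 4.944 in spleen. Its called members were Rgs1 and Bhlhe40 (log2 fold change 2.41 ± 0.41, adjusted p = 0.0333). Of 18 exhaustion-associated genes tested, 3 rose and 0 fell over all genes, and 6 rose and 1 fell over the list alone. The list median was 0.64 (camera adjusted p = 3.59e-08, and 0.059 with an estimated correlation). Id2 rose by 0.80 ± 0.15 (adjusted p = 0.0441). Of 18 inhibitory and costimulatory genes tested, 1 rose and 0 fell over all genes, and 4 rose and 1 fell over the list alone. The list median was 0.24 (camera adjusted p = 0.000955, and 0.139 with an estimated correlation). In egressed 1 to 4 its mean log2 CPM was 4.344, 3.662, 3.065 and 2.418, against 3.585 to 4.148 in spleen. The member that rose was the receptor gene Cd160, at 211 ± 20.4 against 67.8 ± 18.7 CPM (log2 fold change 1.64 ± 0.25, adjusted p = 0.0209). Pdcd1 measured 34.7 ± 12.9 against 12.9 ± 6.13 CPM and did not pass (adjusted p = 0.243). The replicate block ended the calls of Ctsw, Fasl, Klrd1, Klrc1, Klrk1, Bhlhe40 and Id2 (adjusted p = 0.124, 0.129, 0.0628, 0.051, 0.0569, 0.0853 and 0.146). Each of these and of Ccl3 also failed without any 1 spleen library (adjusted p up to 0.234). Cd160 failed without spleen 1, 3 or 4, and all but Ccl3 failed without egressed library 1.

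Neither the homing nor the stem-like list was called in this comparison, and 0 of their members passed over all genes. Adjusted over the list alone, 0 of 14 homing genes rose and 1 fell, and 1 of 18 stem-like genes rose and 3 fell. Lef1, of the stem-like list, measured 301 ± 45.3 against 696 ± 51.5 CPM (log2 fold change -1.21 ± 0.28, adjusted p = 0.114 over all genes and 0.00971 over the list). The homing list had a median of -0.32 (camera adjusted p = 0.614) and the stem-like list of -0.39 (adjusted p = 0.13, but 0.00816 without the 3 libraries that detected the fewest genes). S1pr1 measured 669 ± 133 CPM in egressed and 765 ± 100.1 in spleen cells (95% confidence interval of the log2 fold change -0.75 to 0.36). With the same kind of interval, Ccr7 measured 882 ± 181 and 869 ± 59.3 (-0.72 to 0.76), Tcf7 1384 ± 78.9 and 1814 ± 82.3 (-0.93 to 0.14) and Cxcr4 18.4 ± 8.20 and 15.5 ± 5.31 (-0.81 to 1.30). Among genes lower in egressed cells, the iron exporter gene Slc40a1 had no count in egressed libraries against 11.1 ± 8.02 CPM in spleen. It was at least 98.16-fold lower (adjusted p = 0.0333). In spleen it was highest in libraries 1 and 2 (12.29 and 22.01 CPM), as were macrophage markers (mean log2 CPM 2.289 and 2.314). Spleen macrophages as its source were not tested. Atp13a3, a transport ATPase gene, fell by 1.77 ± 0.26 (adjusted p = 0.0194). The small GTPase gene Arf3 fell by 1.67 ± 0.25 (adjusted p = 0.0193) and Lfng, which modifies Notch receptors, by 1.38 ± 0.22 (adjusted p = 0.0235). With the replicate block the adjusted p was 0.208 for Slc40a1 and 0.103 for Lfng. All 4 calls ended without any 1 spleen library or without egressed library 1 (adjusted p up to 0.152, 0.11, 0.11 and 0.134). Those of Slc40a1, Atp13a3 and Arf3 also ended without egressed library 4.

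Macrophage markers were lower in egressed than in spleen cells, with 0 members called over all genes or when adjusted over the list alone (median -1.81, camera adjusted p = 0.0302, and adjusted p = 0.793 with an estimated correlation). The call of this list ended without egressed library 1 (adjusted p = 0.0812) or 3 (0.186), spleen library 1 (0.0788) or 2 (0.0507), tumor-retained library 3 (0.0600) or 4 (0.0528), and without the 3 libraries that detected the fewest genes (0.116). Of its members, Ctss measured 163 ± 27.2 and 150.3 ± 9.27 CPM, and Lyz2 19.5 ± 32.6 CPM in egressed and 4.995 ± 4.987 in spleen cells, with 68.08 in egressed library 4 and at most 9.03 in the other 3. Stromal markers had a median of 0.17 (adjusted p = 0.93). Dendritic cell markers had a median of 0.98 (adjusted p = 0.374), but passed without egressed library 3 (0.0155) and without the 3 libraries that detected the fewest genes (adjusted p = 1.38e-06).

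The third comparison, tumor-retained against spleen, asks what set cells that stayed in the tumor apart from circulating cells. Tumor-retained cells held more transcripts of inhibitory receptors, exhaustion regulators, residency genes, cytotoxic molecules and glycolytic enzymes, and fewer of homing and stem-like genes. Macrophage and stromal markers (medians 3.24 and 5.60) moved with the glycolysis list, and the homing list lost its call with an estimated correlation (adjusted p = 0.0507). Gzmb measured 1859 ± 413 CPM in tumor-retained and 36.4 ± 22.2 in spleen cells (log2 fold change 5.67 ± 0.45, adjusted p = 7.35e-05). Pdcd1 measured 388 ± 155 against 12.9 ± 6.13 (log2 fold change 4.91 ± 0.50, adjusted p = 0.000217). Rgs1 measured 732 ± 255 against 34.7 ± 7.16 (log2 fold change 4.40 ± 0.30, adjusted p = 3.61e-05). Klf2 fell to 192 ± 85.8 from 663 ± 31.3 CPM (log2 fold change -1.79 ± 0.26, adjusted p = 0.00332). In all, 518 genes changed, 219 higher and 299 lower in tumor-retained cells, 408 of them by more than 2-fold. Of 29 lists, 24 changed, 20 higher and 4 lower, 12 of them also with an estimated correlation. The median change of all genes was -0.151 with TMM scaling, 0.0344 with DESeq2 size factors and -0.105 with library size. With size factors 322 genes were higher and 178 lower, and with DESeq2's test 963 and 1371.

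The count was 223, 251, 237 and 285 without spleen library 1, 2, 3 or 4 and 328 without tumor-retained library 4, and 213 genes passed with every library left out in turn. The replicate block gave 295 genes (134 higher, 161 lower), 292 of them among the 518. Of the 518 genes, 268 passed without tumor-retained libraries 3 and 4 and 506 without the 3 libraries that detected the fewest genes, where 2347 genes passed in all.

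Inhibitory and costimulatory receptors were higher in tumor-retained cells. Of 18 inhibitory and costimulatory genes tested, 8 rose and 0 fell over all genes, and 10 rose and 0 fell when adjusted over the list alone. The list median was 2.29 (camera adjusted p = 6.07e-20, and 0.00169 with an estimated correlation). Icos rose to 741 ± 325 CPM from 71.7 ± 8.92 (log2 fold change 3.37 ± 0.48, adjusted p = 0.00248). Havcr2 did not pass at 111 ± 88.3 against 3.13 ± 0.742 (adjusted p = 0.0865). Of 18 exhaustion-associated genes tested, 7 rose and 1 fell over all genes, and 11 rose and 2 fell when adjusted over the list alone. The list median was 1.83 (camera adjusted p = 1.95e-20, and 0.00271 with an estimated correlation). They included Bhlhe40 (log2 fold change 5.29 ± 0.47, adjusted p = 0.000109), Id2 (log2 fold change 1.79 ± 0.15, adjusted p = 8.84e-05) and Nr4a2 (log2 fold change 4.26 ± 0.52, adjusted p = 0.000993). Tox was the member that fell, from 59.2 ± 11.8 to 18.8 ± 5.45 CPM (log2 fold change -1.66 ± 0.36, adjusted p = 0.0319). The Tox call ended with the replicate block (adjusted p = 0.0832), without tumor-retained libraries 3 and 4 (0.188) and without any 1 library other than egressed 3, egressed 4 or tumor-retained 1 (up to 0.13). Of 18 antigen receptor response genes tested, 5 rose and 1 fell over all genes, and 7 rose and 1 fell when adjusted over the list alone. The list median was 1.92 (camera adjusted p = 1.96e-09, and 0.0232 with an estimated correlation). Nr4a1 rose to 313 ± 180.2 from 44.1 ± 5.17 CPM (log2 fold change 2.82 ± 0.40, adjusted p = 0.00254). The member that fell was Myc, a driver of growth, at 126 ± 43.4 against 331 ± 61.2 (log2 fold change -1.40 ± 0.25, adjusted p = 0.00975). Immediate early and heat-shock genes were higher as well. Of 20 immediate early and heat-shock genes tested, 6 rose and 0 fell over all genes, and 8 rose and 0 fell when adjusted over the list alone. The list median was 0.50 (camera adjusted p = 4.93e-15, and 0.0142 with an estimated correlation). Fos rose by 2.49 ± 0.22 (adjusted p = 0.000109) and Egr1 by 2.07 ± 0.35 (adjusted p = 0.00737, and 0.0547 without tumor-retained libraries 3 and 4).

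Residency, cytotoxic, chemokine receptor and innate-like receptor lists were higher. Of 17 residency genes tested, 6 rose and 0 fell over all genes, and 7 rose and 0 fell when adjusted over the list alone. The residency median was 2.04 (camera adjusted p = 1.98e-29, and 0.00271 with an estimated correlation). Rgs1 and Litaf (log2 fold change 4.52 ± 0.44, adjusted p = 0.0002) were among them. Cd69 (341 ± 146 against 224 ± 5.68 CPM) and Itgae (146 ± 50.2 against 90.2 ± 18.8) did not pass (adjusted p = 0.351 and 0.378). Of 19 cytotoxic genes tested, 10 rose and 0 fell over all genes, and 11 rose and 0 fell when adjusted over the list alone. The list median was 2.11 (camera adjusted p = 3.67e-32, and 0.00169 with an estimated correlation). Ccl3 rose by 4.54 ± 0.47 (adjusted p = 0.000253) and Fasl by 4.49 ± 0.49 (adjusted p = 0.000367). Of 17 chemokine receptor genes tested, 3 rose and 0 fell over all genes, and 5 rose and 2 fell when adjusted over the list alone. The chemokine receptor median was 1.08 (camera adjusted p = 2.29e-06, and 0.0474 with an estimated correlation). Cxcr6 (log2 fold change 2.04 ± 0.25, adjusted p = 0.0011) and Ccr2 (log2 fold change 2.89 ± 0.45, adjusted p = 0.00435) were among those that rose. Of 17 innate-like receptor genes tested, 6 rose and 0 fell over all genes, and 9 rose and 1 fell when adjusted over the list alone. The innate-like receptor median was 2.25 (camera adjusted p = 2.34e-19, and 0.0135 with an estimated correlation). Klrk1 measured 807 ± 199 against 77.2 ± 22.5 CPM (adjusted p = 0.000109) and Klrc1 561 ± 149.6 against 47.5 ± 16.7 (adjusted p = 0.0002). Of 15 circulating effector genes tested, 3 rose and 1 fell over all genes, and 6 rose and 1 fell when adjusted over the list alone. The circulating effector median was 0.05 (camera adjusted p = 0.00637, and 0.257 with an estimated correlation), with a mean of 0.50. The member that fell was Klf2, while Klrg1 and Cx3cr1 did not pass (adjusted p = 0.934 and 0.716).

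Homing and stem-like genes were lower in tumor-retained cells. Of 14 homing genes tested, 0 rose and 4 fell over all genes, and 1 rose and 9 fell when adjusted over the list alone. The homing median was -0.82 (camera adjusted p = 1.34e-05, and 0.0507 with an estimated correlation). Of 18 stem-like genes tested, 0 rose and 6 fell over all genes, and 0 rose and 10 fell when adjusted over the list alone. The stem-like median was -0.95 (camera adjusted p = 2.25e-11, and 0.0249 with an estimated correlation). Lef1, a transcription factor of stem-like T cells, fell to 149 ± 81.3 from 696 ± 51.5 CPM (log2 fold change -2.23 ± 0.29, adjusted p = 0.00154). Il6ra fell to 18.8 ± 4.25 from 115 ± 16.6 (log2 fold change -2.62 ± 0.27, adjusted p = 0.000253). Tcf7, which encodes TCF-1, fell to 853 ± 393 from 1814 ± 82.3 (log2 fold change -1.09 ± 0.25, adjusted p = 0.0414). It did not pass with the replicate block (adjusted p = 0.0585) nor without any 1 library other than egressed 3 or tumor-retained 1 (up to 0.119). S1pr1 measured 396 ± 178 against 765 ± 100.1 CPM (adjusted p = 0.0805) and Ccr7 453 ± 273 against 869 ± 59.3 (adjusted p = 0.171), and neither passed. The genes with the largest decreases included Slc16a5, with 2 counts in tumor-retained cells which gave a ratio of 4111 in spleen over tumor-retained (95% counting interval 1138 to 33950, adjusted p = 2.1e-05). Also among them were Art2b (log2 fold change -6.33 ± 0.89, adjusted p = 0.00233), Dtx1 (log2 fold change -4.60 ± 0.60, adjusted p = 0.00153) and Dapl1 (log2 fold change -4.04 ± 0.39, adjusted p = 0.0002).

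Glycolytic enzymes were higher in tumor-retained cells. Of 16 glycolysis genes tested, 8 rose and 0 fell over all genes, and 11 rose and 0 fell when adjusted over the list alone. The glycolysis median was 1.13 (camera adjusted p = 7.58e-20, and 0.0294 with an estimated correlation). Gapdh rose to 1604 ± 371 from 571 ± 33.7 CPM (log2 fold change 1.49 ± 0.17, adjusted p = 0.000503). Tpi1 rose to 479 ± 238 from 97.0 ± 9.78 (log2 fold change 2.30 ± 0.41, adjusted p = 0.00965). Tpi1 did not pass without spleen library 1 (adjusted p = 0.0538) nor without tumor-retained libraries 3 and 4 (0.0833). Of 17 hypoxia response genes tested, 3 rose and 1 fell over all genes, and 6 rose and 1 fell when adjusted over the list alone. The hypoxia response median was 2.10 (camera adjusted p = 1.35e-08, and 0.0679 with an estimated correlation). Mxi1 measured 101 ± 41.5 against 23.5 ± 4.75 CPM (log2 fold change 2.10 ± 0.32, adjusted p = 0.00424, and 0.0669 without tumor-retained libraries 3 and 4). The member that fell was Pdk1, a kinase that limits entry of pyruvate into mitochondria (log2 fold change -1.27 ± 0.24, adjusted p = 0.013), though not without spleen library 2 or tumor-retained library 1 (adjusted p up to 0.0513). Without tumor-retained libraries 3 and 4 the median was 0.53 for glycolysis (adjusted p = 2.23e-08) and 0.57 for hypoxia (adjusted p = 0.00266). Of 18 macrophage marker genes tested, 0 rose and 0 fell over all genes, and 6 rose and 0 fell over the list alone. The macrophage marker median was 3.24 (camera adjusted p = 5.18e-05, and 0.299 with an estimated correlation). Of 13 stromal marker genes tested, 1 rose and 0 fell over all genes, and 8 rose and 1 fell over the list alone. The stromal marker median was 5.60 (camera adjusted p = 1.29e-05, and 0.145 with an estimated correlation). Without those 2 libraries neither list passed (adjusted p = 0.684 and 0.0662). Col3a1 was the stromal gene called, at 408 ± 467 against 0.923 ± 0.300 CPM (log2 fold change 8.78 ± 1.92, adjusted p = 0.0333). Its adjusted p was 0.165 with the replicate block, 0.266 without the 2 libraries and up to 0.139 without any 1 library other than egressed 3 or 4 or tumor-retained 1 or 2. Genes with the largest increases were in part of the same kind. Cxcl1, a chemokine gene of myeloid and stromal cells, had 1 count in spleen and 217 ± 249 CPM in tumor-retained cells (ratio 25370, 95% counting interval 4553 to 1002000, adjusted p = 0.0213). Spp1, for osteopontin, measured 3861 ± 6041 against 0.662 ± 0.416 CPM (adjusted p = 0.0285). With the block their adjusted p was 0.0769 and 0.162. Without the 2 libraries it was 0.239 and 0.295, and without any 1 spleen library or tumor-retained library 4 up to 0.158 and 0.124. Ier5l (log2 fold change 6.22 ± 0.63, adjusted p = 0.000226) and Lilr4b (log2 fold change 5.84 ± 0.60, adjusted p = 0.000253), a gene with a close relative in Lilrb4a, rose under all of these settings.

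**Figure D3:**
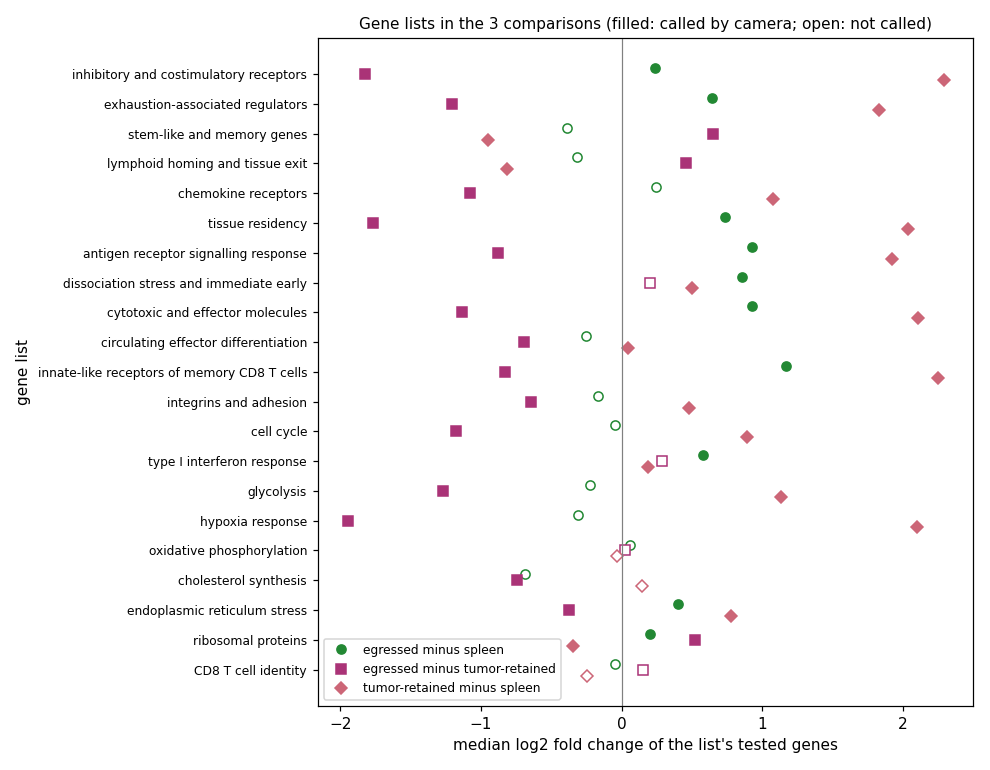
Median log2 fold change (x axis) of the tested genes of 21 lists (y axis) in the 3 comparisons, with filled symbols where camera called the list at its preset correlation and open symbols where it did not. Inhibitory receptors lie at -1.82 in egressed minus tumor-retained, 0.24 in egressed minus spleen and 2.29 in tumor-retained minus spleen.

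Changes shared between comparisons were counted next. Of the 79 genes that differed between egressed and spleen cells and the 518 that differed between tumor-retained and spleen cells, 57 were called in both in the same direction (35 higher, 22 lower than spleen) and 0 in opposite directions. Independent lists of these sizes would share 0.944 genes, and 10 simulations of unchanged groups against the same spleen libraries shared 0. With the spleen libraries divided between the comparisons, 2 for each, the 6 divisions shared 1 to 4 genes (median 2, against 0.00573 for independent lists). Only 2 and 142.5 genes were called in the median division. The replicate block gave 17 shared genes, and leaving out 1 library gave 5 without spleen 1 and up to 73. Between the calls of tumor-retained against egressed and against spleen cells, 157 genes were shared in the same direction (80 higher, 77 lower in tumor-retained cells) and 0 in opposite directions. Independent lists would share 2.80, and unchanged groups shared 0, which was again all but fixed in advance. With the tumor-retained libraries divided, 24 to 115 genes were shared (median 52.5, against 0.691 for independent lists). The calls were 108.5 and 301 in the median division, and the block gave 64. The share of all tested genes with the same sign was 59.3% in the first pair and 75.4% in the second, where simulated unchanged groups gave 66.8% and 66.7%.

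The position of egressed cells on the axis from spleen (0) to tumor-retained cells (1) was measured mouse by mouse, with the genes and their changes taken from the other 3 mice. It was 0.325, 0.296, 0.264 and 0.369 for mice 1 to 4 over 175 to 251 genes, with a mean of 0.314 ± 0.0444 (SD, n = 4). With 4 mice the smallest exact 2-sided sign-flip p stays above 0.05, so no test was made. In simulated data a position of 0 gave -0.0103 and a position of 0.5 gave 0.394, so the measure understated positions. Leaving out 1 mouse left a value for 1 of the other 3 mice only, because the remaining fits called fewer than 10 genes. It was 0.0745 without mouse 1 and 0.0555 without mouse 2 (92 genes each). Both values took genes and axis from mice 3 and 4 alone, whose tumor-retained libraries held transcripts of other cells. The value was 0.225 without mouse 3 and 0.260 without mouse 4 (77 genes each), with genes and axis from mice 1 and 2 alone.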

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

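No test in this part was chosen after the results were seen. In 38 of 678 groups of 4 libraries, 1 library lay so far from the other 3 that its distance to the nearest took most of the group's range (Dixon's rule), where chance gives about 1 in 20 groups, or 33.9. The values below are in CPM. In spleen, Cxcl1 was 0.03 and Ccl4 28.79, Sphk1 1.58 and Tnfaip3 165.75 in library 1, Bhlhe40 was 22.01, Cd160 95.59, Rasgrp2 231.82 and Ube2c 14.09 in library 2, Ccr7 was 957.73, Dcn 0.03 and Irf7 273.97 in library 3, and Klrd1 was 235.81 and S1pr1 615.71 in library 4. In egressed cells, Alas2 was 3.87, C1qc 0.66, Cd14 0.27, Dcn 2.81, Sox13 4.5 and Stk32c 0.04 in library 1, Cxcl1 was 0.64, Hmox1 0.11, Igfbp3 0.53 and Irf7 281.52 (407.63 to 414.38 in the others) in library 2, Klra8 was 6.67 in library 3, and Cd5 was 317.8, Lyz2 68.08 and Bambi-ps1 0 (11.04 to 12.04 in the others) in library 4. In tumor-retained cells, Bambi-ps1 was 0.03 in library 1, Cd209a was 0.18, Dapl1 31.67 and Pmel 19.01 in library 2, Esm1 was 116.85, Hspa1b 3362.71 (732.53 to 855.55 in the others), Igfbp3 1059.45 and Lfng 64.91 in library 3, and Cx3cr1 was 16.09 and Mmp9 48.36 in library 4. The number of genes detected was 15296 in tumor-retained library 1 and 20560 to 21306 in the other 3 of that group.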

How the results depend on the processing

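The fits without tumor-retained libraries 3 and 4, without the 3 libraries that detected the fewest genes, and with limma-voom weights were chosen after seeing the data, and all other alternatives were planned. Where a value changed, the cause was not tested. Counts of changed genes are given in the order egressed against tumor-retained (235), egressed against spleen (79) and tumor-retained against spleen (518). DESeq2 gave 2622, 661 and 2334 genes and limma on the deposited log2 values 378, 224 and 791. The 2 compared groups alone gave 13, 230 and 1304, the replicate block 78, 23 and 295, and glmTreat 45, 7 and 186. No low-count filter gave 41 and 342 in the comparisons with spleen, limma-voom weights gave 580 and 2750 there, and the fit without the 3 libraries with the fewest genes gave 442 for egressed against tumor-retained and 2347 for tumor-retained against spleen. With 1 library left out the counts ranged from 95 to 487, 5 to 123 and 223 to 645. The other settings stayed within 1.5 times.

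Of the 21, 11 and 24 lists called, 1, 2 and 12 were called with an estimated correlation and 12, 2 and 14 by fry, and the other settings stayed within 1.5 times. The block added CD8 identity and interferon for egressed against tumor-retained (adjusted p = 0.0461 and 0.0461) and oxidative phosphorylation for egressed against spleen (0.0339), ended B cell and dendritic cell markers for tumor-retained against spleen (0.0682 and 0.0702), and changed no other call of a list. Without tumor-retained libraries 3 and 4, and beside the losses given elsewhere, egressed against tumor-retained lost cholesterol (0.273) and endoplasmic reticulum stress (0.457) and gained immediate early genes (0.0127), and tumor-retained against spleen lost dendritic cell (0.821) and ribosomal genes (0.0507) and gained CD8 identity (0.0197). Without the 3 libraries with the fewest genes, interferon was gained against tumor-retained cells (0.0472), natural killer genes in egressed against spleen (0.000236) and CD8 identity in tumor-retained against spleen (0.0293), where interferon (0.104) and B cell genes (0.184) were lost. Size factors or library size gained CD8 identity (0.0233 and 0.0474) and oxidative phosphorylation (0.00177 and 0.0039) in egressed against spleen, and both lost dendritic cell genes (0.112 and 0.0546) in tumor-retained against spleen. The overlap of calls against spleen (57) was 33 without the filter, 326 with DESeq2, 150 with limma, 96 with 2 groups, 17 with the block, 7 with glmTreat and 368 with voom weights, and 5 to 73 with 1 library left out. The overlap of calls of tumor-retained cells (157) was 1240 with DESeq2, 13 with 2 groups, 64 with the block, 38 with glmTreat and 364 without the 3 libraries with the fewest genes, and 67 to 277 with 1 library left out. The position of egressed cells (0.314) was 0.266 without the filter, 0.315 with size factors, 0.319 with library size, 0.270 over 500 genes and 0.308 with a prior count of 0.5. With 1 mouse left out it was 0.0555 to 0.260. The lower values (0.0555 and 0.0745) took genes and axis from mice 3 and 4 alone, whose tumor-retained libraries held transcripts of other cells.

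Changes of sign occurred for genes that passed no test, with a lowest adjusted p of 0.2998 among the reversed values. In egressed minus tumor-retained, Cxcr4 was 0.00179 with library size, 0.16 without the 2 tumor-retained libraries and 0.13 without the 3 libraries (-0.32 to 0.11 with 1 left out), Klrg1 -0.26 with limma, -0.0141 without the 3 libraries and -2.10 with voom (-0.0795 to 1.21), and, without the 2 libraries, Cx3cr1 1.30 (-3.13 to 1.01) and Cd14 2.02. In egressed minus spleen, Klf2 was -0.00598 without the 2 libraries, -0.14 without the 3 and -0.0722 with voom (-0.0581 to 0.102), Ccr7 -0.0324 with the block (-0.06 to 0.13), and Itgae -0.14 without the 3 libraries and -0.0336 with voom (-0.21 to 0.45). Mki67 was 0.12 with size factors, 0.11 with library size, 0.12 with DESeq2, 0.0141 with 2 groups, 0.64 without the 3 libraries and 0.0468 with voom (-0.45 to 0.40). In tumor-retained minus spleen without the 2 libraries, H2-Eb1 was -1.53, Cd14 -5.16, Lyz2 -0.78, H2-Ab1 -0.57 and Sparc -0.37. Depth limits what is seen below about 0.132 CPM, the highest limit that a count of 0 allows.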

Other observations

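All tests of explanations in this part were chosen after the results were seen, whereas the list tests were planned. Several lists not described above also moved, with values given as median log2 fold change and camera adjusted p in the order egressed minus tumor-retained, egressed minus spleen, tumor-retained minus spleen. Cell cycle genes were highest in tumor-retained cells as a group (-1.18, -0.05 and 0.90, adjusted p = 0.000474, 0.909 and 0.000817, and 0.263, 0.982 and 0.293 with an estimated correlation). Their mean log2 CPM was 5.951 and 5.655 in tumor-retained libraries 3 and 4, but 3.331 and 3.532 in 1 and 2, against 4.171 to 5.017 in spleen. The centromere histone gene Cenpa rose to 151 ± 33.3 CPM from 52.9 ± 9.61 in spleen (adjusted p = 0.00762, and 0.0821 without tumor-retained libraries 3 and 4) but Mki67 was not called (52.1 ± 31.0 against 23.3 ± 10.4 CPM). Neither call of the list held without tumor-retained libraries 3 and 4 (adjusted p = 0.208 and 0.195). Interferon response genes were called higher than in spleen in both red populations (0.29, 0.58 and 0.19, adjusted p = 0.0721, 8.7e-11 and 0.00149, and 0.572, 0.0753 and 0.293 with an estimated correlation). Their mean log2 CPM lay above all spleen libraries (5.102 to 5.549) only in egressed 1 (6.454) and tumor-retained 1 (6.136). In tumor-retained cells the call ended without tumor-retained library 1 (0.208). The member that rose there was Isg20, to 63.2 ± 25.0 from 21.1 ± 4.99 CPM (adjusted p = 0.0234). Its call ended with the replicate block (adjusted p = 0.11) and without any 1 spleen library (up to 0.108). Endoplasmic reticulum stress genes changed in each comparison (-0.37, 0.40 and 0.78, adjusted p = 0.00657, 1.01e-05 and 1.93e-09, and 0.263, 0.138 and 0.0294 with an estimated correlation). Their mean log2 CPM was 7.211 and 6.638 in tumor-retained libraries 3 and 4, but 5.838 and 5.628 in libraries 1 and 2. It was 5.637 to 5.998 in spleen. Xbp1, of the unfolded protein response, rose to 227 ± 67.2 from 68.4 ± 7.93 CPM in spleen (adjusted p = 0.00623, and 0.0408 without tumor-retained libraries 3 and 4). The call against tumor-retained cells ended without tumor-retained library 3 (0.0583). Ribosomal protein genes were higher in egressed than in the other groups (0.53, 0.20 and -0.35, adjusted p = 8.18e-15, 3.59e-08 and 0.00131, and 0.134, 0.453 and 0.479 with an estimated correlation). The fall in tumor-retained cells against spleen was lost with DESeq2 size factors (adjusted p = 0.129) and without egressed library 2 (0.0558) or 4 (0.0704) or tumor-retained library 2 (0.0715) or 4 (0.0983). Integrins moved as a list without a single member passing (-0.64, -0.17 and 0.48, adjusted p = 0.000474, 0.52 and 0.00611, and 0.0829, 0.878 and 0.132 with an estimated correlation). Cholesterol synthesis was called against tumor-retained cells (-0.74, -0.68 and 0.14, adjusted p = 0.0188, 0.0534 and 0.439, and 0.263, 0.548 and 0.697 with an estimated correlation). The cholesterol call ended without egressed 2 (0.0604) or tumor-retained 4 (0.0628), and in egressed minus spleen the list was gained without egressed 1 (0.0398), egressed 3 (0.0279), spleen 2 (0.0367) or spleen 4 (0.0328). Oxidative phosphorylation (0.03, 0.06 and -0.03, adjusted p = 0.767, 0.0806 and 0.235) and CD8 T cell identity (0.15, -0.04 and -0.24, adjusted p = 0.0562, 0.374 and 0.353) were not called with all libraries. Leaving out 1 library gained CD8 identity in egressed minus tumor-retained without egressed 1 (0.0464), egressed 2 (0.0198), tumor-retained 1 (0.000134) or tumor-retained 2 (0.0499), in egressed minus spleen without egressed 2 (0.0188) and, downwards, in tumor-retained minus spleen without tumor-retained 1 (0.0119). It gained oxidative phosphorylation in egressed minus spleen without egressed 2 (0.00705) or tumor-retained 1 (0.0213) and in tumor-retained minus spleen without egressed 4 (0.049) or tumor-retained 2 (0.0194), and interferon in egressed minus tumor-retained without egressed 2 (0.00246) or tumor-retained 1 (5.36e-05).

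Markers of other cells beyond those in the report gave, in the same order, B cell genes 1.52, 0.39 and -0.80 (adjusted p = 0.00453, 0.614 and 0.0161), and dendritic cell genes -0.81, 0.98 and 2.00 (0.238, 0.374 and 0.0442). Granulocyte genes at -3.44, 0.47 and 2.94 (0.635, 0.614 and 0.358) did not pass. Natural killer and gamma delta T cell genes had -0.56, 0.94 and 1.85 (0.238, 0.13 and 0.013), and melanoma genes -0.01, -0.40 and 0.47 (0.952, 0.859 and 0.982). CD4 and regulatory T cell genes had 0.91 and 2.16 against spleen (0.374 and 5.18e-05). With an estimated correlation the calls among these had adjusted p = 0.263 and 0.299 for B cell, 0.479 for dendritic cell, 0.293 for natural killer and 0.0232 for CD4 genes, the last by Capg and Ctla4. Natural killer genes were gained in egressed minus spleen without egressed 3 (0.0279), egressed 4 (0.0114) or spleen 2 (0.0434), and granulocyte genes in tumor-retained minus spleen without tumor-retained 2 (0.0334). The B cell call against spleen ended without tumor-retained library 1 (0.123) and the dendritic call without egressed library 2 (0.0535) or 4 (0.0502) or tumor-retained library 3 (0.113) or 4 (0.119). Median, mean and test differed in sign for some uncalled lists. Against tumor-retained cells the mean was -0.36 for immediate early and heat-shock genes (median 0.20, adjusted p = 0.152), 0.32 for natural killer and 0.23 for melanoma genes. Against spleen, egressed cells had a mean of -0.49 for chemokine receptors (median 0.25, adjusted p = 0.388) and -0.57 for CD4 genes. The test pointed to higher values for circulating effector (-0.25, adjusted p = 0.812), glycolysis (-0.23, 0.947) and CD8 identity genes. It did so in tumor-retained against spleen for oxidative phosphorylation, where melanoma genes had a median above 0 and a mean of -0.52, and hypoxia genes of egressed against spleen cells had -0.31 (0.833). Ighm, the constant region gene of IgM, measured 687 ± 64.0 CPM in spleen, 615 ± 37.5 in egressed and 114 ± 12.7 in tumor-retained cells. Its log2 fold change was 2.43 ± 0.12 in egressed minus tumor-retained (adjusted p = 2.81e-06) and -2.59 ± 0.12 in tumor-retained minus spleen (adjusted p = 1.42e-06). The B cell genes Cd79a and Igkc stayed at or below 9.49 and 15.76 CPM in every library, but Cd79b reached 33.79 CPM and Cd22 was 78.62 to 158.54 CPM in egressed, 21.28 to 37.29 in spleen and 0.03 to 29.82 in tumor-retained libraries.

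Tumor-retained libraries 3 and 4 held transcripts that were low in the other 10, although the CD44+ CD8+ gate would remove cells without CD8. Of 31 macrophage and stromal genes, 25 (15 of 18 and 10 of 13) were higher in both libraries than in every other (Sparc at 1287 and 357.9 CPM, Fn1 at 1142 and 655.0, Cd74 at 694.8 and 1082), although 3 of the 18 macrophage and 1 of the 13 stromal genes exceed 10 CPM in spleen T cells and 0 and 0 stand in another list. Since the libraries were singled out by such transcripts and the bound was written afterwards, this count could hardly have come out otherwise, and macrophages, stromal cells and melanoma cells as sources (3 of 10 melanoma genes, and Y-linked sums of 36.8 and 46.17 CPM against at most 0.11 elsewhere, which male cells would bring) cannot be told apart. Without both libraries the glycolysis median in tumor-retained minus spleen was 0.5255 (1.13 with them, adjusted p = 2.23e-08), so part of it may come from such cells, which cannot be told apart from a change in T cells. The inhibitory receptor median was 1.838 (2.29 with them, adjusted p = 3.65e-17), which argues against such cells as its whole source.

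The higher immediate early and heat-shock list in egressed than in spleen cells may reflect activation, or handling of the lymph node. Fewer genes captured in egressed libraries 3 and 4 were excluded as the whole source, since without the 3 libraries that detected the fewest genes the median was 0.9796 (0.8554 with them, adjusted p = 2.85e-28). Handling cannot be told apart from signals received in the tissue: the 8 heat-shock members had a median of 0.2179 (7 above 0), the 12 immediate early members 1.005 (12 above 0) and the 18 genes of the antigen receptor response 0.9314 (13 above 0), and tissue differs with group.

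Other splits of the 8 libraries of each comparison into 4 and 4 gave, for genes, a count as large as the real one in 2 of 35 splits for egressed against tumor-retained, the real one included (235, highest other 316), so chance could not be excluded there. It did so in 1 of 35, the smallest share possible, for egressed (79) and for tumor-retained (518) against spleen, with a highest other of 0. For lists the share was 1 of 35 for egressed against tumor-retained (21, highest other 19). It was 6 of 35 for egressed (11, highest other 13) and 2 of 35 for tumor-retained (24, highest other 25) against spleen. An unadjusted share of 1 in 35 argues against chance only if same-numbered libraries are unpaired. The split with 316 genes set egressed 1 and 2 with tumor-retained 3 and 4 against the other 4 libraries. Those other 4 include the 3 that detected the fewest genes, and the cause of that count was not tested. Among the 8 splits that part every pair of a mouse, too few for a share under 0.05, the highest others were 316, 0 and 0 genes and 19, 12 and 23 lists.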
